A study of Mus musculus with 9 samples.

How the data were processed

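Total RNA of 1 liver per mouse was labelled by reverse transcription and in vitro transcription and hybridised to Affymetrix arrays, 1 array per mouse and 3 mice per group. Age at death was 11 weeks, and injections were 100 µl of corn oil with or without compound. Groups and replicate numbers follow the labels; the labels call the controls untreated and the design text says that they received corn oil. The deposited values are signal intensity per probe set, on a linear scale, made by the authors with GCOS, the Affymetrix software, whose version the submitters' processing notes do not give. Each array had been scaled by the authors so that its mean, without the top and bottom 2% of probe sets, was 500.0. No detection calls were used here. The 36 pairs of arrays were checked for identical columns and none was found.

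The 64 control probe sets of the manufacturer were left out of the tests and used for the 3'/5' ratios of actin, Gapdh and pyruvate carboxylase. Of the remaining probe sets 34945 carry 1 gene symbol, 932 carry several and 9160 carry none in the annotation of the array. Gene identifiers matched the RefSeq gene table for 34741, and 0 symbols changed. Signals under the 25th percentile of their array were raised to that percentile, and log2 was taken. Probe sets above the array median on at least 3 arrays were kept, which left 25146 with 9 arrays and 24531 with 8, for 12541 and 12293 genes. Where 1 probe set stands for a gene, it is the kept one with the highest mean. Array medians lay between 157 and 186, and at 214 on DCAA 3.

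Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with all groups in 1 model and no covariate. DCAC and DCAA were each compared with control and with each other, and all treated mice were compared with control in a model of 2 groups. Calls have a two-sided Benjamini-Hochberg adjusted p under 0.05 over all probe sets kept. The median 95% interval of a probe set reached 1.64-fold either way with 9 arrays and 1.56-fold with 8, for a compound against control. Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over all lists. There were 41 lists, 27 of pathways and 14 of cell type markers, and those with fewer than 5 measured genes were not tested. The correlation of both fold changes was set beside 20 simulations of unchanged groups with shared controls.

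The groups, tests, gene lists, named-gene rule and alternatives were fixed before the data were examined. The fit of 8 arrays, the 3'/5' ratio class and the tests that use them were added after the data were seen. The class divides the arrays at the largest gap in the pyruvate carboxylase ratio. Named genes are up to 12 per direction for each compound against control and up to 6 per direction for the other comparisons, with 1 symbol and no overlap between the groups. Genes past the threshold come first by fold change, and then genes of at least 1.5-fold by p. Up to 4 members per list are named, and Gstz1, the Pdk genes and Cyp2e1 whatever their values. Expressed sequence tags and predicted genes were counted and not named.

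Alternatives were quantile normalization, a common median, no floor, an offset of 32, no filter, a filter on every array, 1 probe set per gene, eBayes without trend, robust eBayes, array weights, only the groups compared, replicate number as a block and leaving out each array. Deviations of arrays with the same replicate number correlated between -0.0568 and 0.0356 across groups with 9 arrays, within the range of other numbers, so the numbers were not taken to pair the mice. The tests were run on simulated data of the same size and spread with 200 changed probe sets. With 9 arrays 0 of those changed 2-fold and 68.0% of those changed 4-fold were recovered for DCAC, and with 8 arrays 28.5% and 76.0%. The simulation gave every array the same spread, while the real array control 2 stood far from the rest. The shares with 9 arrays thus do not give the power of the real data. There Saa2, at 42.7-fold with DCAC, did not pass (limma adjusted p = 0.765). False calls with 8 arrays were 8 beside 57 recovered at 2-fold and 13 beside 152 at 4-fold for DCAC. For DCAA they were 2 beside 35 and 19 beside 148. With nothing changed, 1 probe set was called for DCAC and 2 for DCAA.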

Results

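Liver gene expression was measured in 9 female MRL +/+ mice, a strain prone to autoimmune disease. The mice received dichloroacetyl chloride (DCAC), dichloroacetic anhydride (DCAA) or corn oil alone, with 3 mice in each group. Both compounds carry the dichloroacetyl group, with chloride as the leaving group in DCAC and dichloroacetate in DCAA. Each was given at 0.2 mmol/kg by intraperitoneal injection over 6 weeks, and livers were taken 24 h after the last dose. One array per mouse gave a signal for each probe set. Arrays have no read depth, so the number of mice limits the precision.

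The library labelled control 2 stood apart from the rest. Its median Spearman correlation with the other arrays was 0.806, and the other 8 arrays correlated with each other at 0.859 to 0.929. Transcripts of most secreted liver proteins examined were far lower on it. The signal of Ttr, which encodes the plasma protein transthyretin, was 22.1 on control 2 and 42541 to 64893 on the other arrays. Fgb, the fibrinogen beta chain, read 8.80 against 44848 to 60761, and Alb, albumin, read 1678 against 43741 to 65450. Apob, an apolipoprotein, kept more, at 3610 against 23275 to 30401. Hnf4a, a transcription factor of hepatocytes, read 12777 on control 2, within the 9429 to 15132 of the others. Each comparison was therefore made with all 9 arrays, as the design was fixed, and with the 8 arrays without control 2. The second set was chosen after the data were seen and leaves 2 controls.

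A second difference between arrays followed the groups in part. The ratio of 3' to 5' signal of the pyruvate carboxylase control probe sets, a measure of RNA and labelling quality, was 2.85 to 3.99 on 5 arrays. Those were the 3 controls, DCAC 1 and DCAC 2. It was 6.43 to 12.8 on the other 4, which were DCAC 3 and the 3 DCAA arrays. The actin ratio divided the arrays in the same way, at 1.27 to 1.51 against 1.76 to 2.59. No DCAA array had a low ratio and no control had a high ratio.

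**Figure D1:**
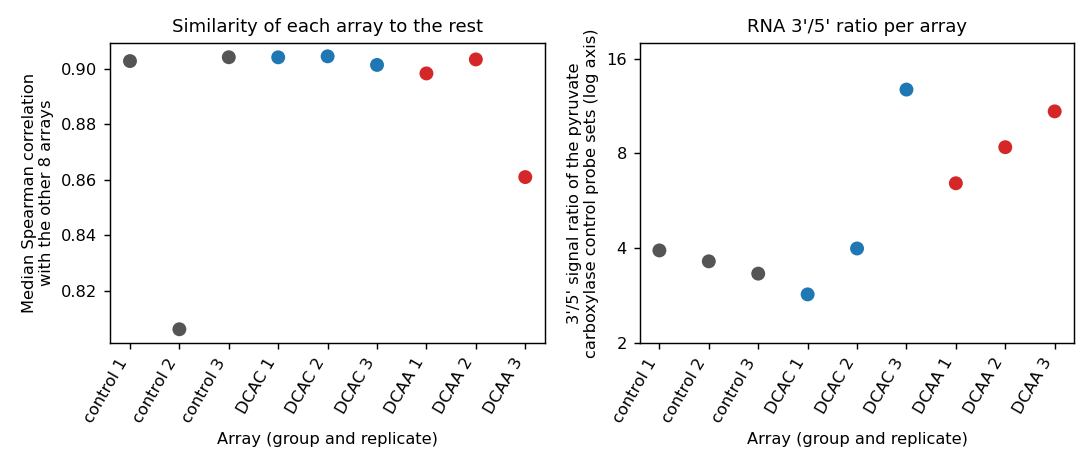
Left, the median Spearman correlation of each array with the other 8; right, the 3'/5' signal ratio of the pyruvate carboxylase control probe sets on a log axis. Each point is the array of one mouse; control 2 lies at 0.806 on the left, and DCAC 3 and the DCAA arrays lie at 6.43 to 12.8 on the right.

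The comparison of DCAC with corn oil asks which liver transcripts differ after repeated exposure to the acyl chloride. Without control 2, genes of the acute phase response, the set of plasma protein genes that the liver raises in inflammation, rose most. Saa2, a serum amyloid A gene, had a mean signal of 37969 ± 8348 (SD, n = 3) with DCAC and 1549 ± 11.0 (SD, n = 2) in controls, a rise of 24.1-fold. Saa1 rose 16.9-fold, Lcn2, which encodes the iron-siderophore binding protein lipocalin 2, 13.2-fold, and Orm2, an orosomucoid gene, 10.8-fold. The metallothionein genes Mt2 and Mt1, whose products bind zinc, rose 4.56-fold and 2.72-fold. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose 4.10-fold, from 2392 ± 1177 (SD, n = 2) to 9398 ± 2504 (SD, n = 3), by its brighter probe set; the other stood at 0.93 in log2 and did not pass.

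In log2 units these changes were 4.59 (SE 0.57) for Saa2, 4.08 (SE 0.40) for Saa1, 3.72 (SE 0.41) for Lcn2, 3.43 (SE 0.40) for Orm2 and 2.03 (SE 0.28) for Cyp7a1. The limma adjusted p was 0.0149, 0.00308, 0.00602, 0.00843 and 0.0312 in that order, and 0.0159 for Mt2 and 0.0349 for Mt1. For each of the 7 genes all 3 DCAC arrays lay above both controls. In all, 8 probe sets of these 7 genes rose and 0 fell among 24531 tested, and 1232 had an unadjusted p under 0.05 where 1227 would by chance. Genes that did not pass included Prtn3, a neutrophil serine protease, at 2.77 (adjusted p = 0.0648). The 2 controls lay far apart for Prtn3, 1 of them at the floor, and its change ran from 1.75 to 3.79 across the alternatives. Cyb561 at 2.25 (0.0584) and Nnmt, nicotinamide N-methyltransferase, at 1.43 (0.0600) did not pass either. On the negative side, Angptl8 stood at -1.89 (0.0954), Ass1, argininosuccinate synthase of the urea cycle, at -1.38 (0.176) and Srebf1, a regulator of lipogenesis, at -0.81 (0.344).

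Of 35 acute phase genes measured, 6 rose over all genes tested and 16 adjusted over the list alone, none fell, and the list's median was 0.31 (0.19 to 0.38 across the alternatives, as in the brackets below). Its camera adjusted p was 3.92e-13, and its adjusted p was 0.381 with an estimated correlation. Of 33 complement and coagulation genes, with a median of 0.28 (0.13 to 0.35), none passed over all genes and 2 rose adjusted over the list alone. C8a and C9, of the membrane attack complex, stood at 0.66 and 0.59. Of 11 neutrophil markers, with a median of 0.78 (0.57 to 0.87), Lcn2 rose over all genes and 3 rose adjusted over the list alone. Lcn2 is also on the acute phase list. Markers of NK and cytotoxic cells had a median of -1.16 (-1.38 to -0.49) over 7 genes, none passing over all genes and 3 lower adjusted over the list alone. Ccl5, a chemokine, stood at -2.46 and the granzyme Gzma at -1.71. The 9 genes of MHC class II presentation had a median of -0.48, with H2-Aa at -1.07, the 1 member that passed adjusted over the list alone; the list was called in 11 of 23 settings, with medians of -1.15 to -0.19. Interferon response genes had a median of -0.27 (-0.57 to -0.019, the last without control 3) over 31, and none passed either way. Other lists without a member that passed either way were hepatocyte markers, with a median of 0.20 (-0.019 to 0.32) over 16, oxidative phosphorylation at 0.11 (-0.011 to 0.17) over 72, and ribosomal protein genes at 0.19 (0.048 to 0.24) over 40. The same held for heat shock genes at -0.20 (-0.40 to -0.024) over 18, markers of Kupffer cells and macrophages at -0.40 (-1.20 to 0.45) over 23, and endothelial markers at -0.36 (-0.57 to -0.0049) over 14. The direction thus turned for hepatocyte markers and oxidative phosphorylation with quantile normalization, and for Kupffer cell and macrophage markers and, by camera, interferon response genes without control 3. No control has a high 3'/5' ratio, so the ratio class as a block leaves DCAC 3 out of the size of this change. That change then rests on DCAC 1 and 2 against the controls, as in the fit without DCAC 3. With the block the calls of 5 of these lists were lost. Their camera adjusted p was 0.923 (endothelial), 0.255 (Kupffer cell and macrophage), 0.197 (hepatocyte), 0.295 (oxidative phosphorylation) and 0.135 (MHC class II). All these lists were among 12 of 40 that camera called, 6 up and 6 down. None was called with an estimated correlation, where the adjusted p of the lists after the acute phase genes ran from 0.557 to 0.80. On the same 8 arrays, camera at the preset correlation called lists in 9 of 10 splits of the DCAC and DCAA arrays, up to 12. A call at that correlation thus does not by itself set a comparison apart from other splits.

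With all 9 arrays limma called 0 of 25146 probe sets, with 1336 at an unadjusted p under 0.05, and the log2 change of Saa2 was 5.42 (95% interval 3.62 to 7.22, adjusted p = 0.765). Without control 2, the count of 8 became 3 without control 1, 5 without control 3, 5 without DCAC 2, 2 without DCAC 3 and 14 without DCAA 1, and 2 with the 3'/5' ratio class as a block; the 12 lists became 7 without DCAC 3.

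The comparison of DCAA with corn oil asks the same of the anhydride. Without control 2, the same 4 acute phase genes led among those that passed, by the brightest probe set of each gene. The rises were 15.8-fold for Saa2, 13-fold for Saa1, 11.3-fold for Lcn2 and 7.73-fold for Orm2 (n = 3 against 2). Mt2 rose 4.45-fold and Mt1 2.99-fold. With the dimmer of its 2 probe sets Mt1 rose by 3.09 in log2, above the 2.95 of Orm2. Angptl4, an inhibitor of lipoprotein lipase, rose 2.81-fold, from 1067 ± 31.4 (SD, n = 2) to 3001 ± 215 (SD, n = 3). The chemokine gene Cxcl1 rose 2.33-fold, and Apcs, which encodes serum amyloid P, 2.02-fold. Srm, spermidine synthase, fell by 1.20 on the log2 scale, the zinc transporter gene Slc39a7 by 1.19 and Slc16a1, a monocarboxylate transporter, by 0.97.

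The log2 change was 3.98 (SE 0.57, limma adjusted p = 0.0227) for Saa2 (4.84 without DCAA 1), 3.70 (SE 0.40, 0.00586) for Saa1, 1.49 (SE 0.21, 0.0227) for Angptl4 and 1.22 (SE 0.15, 0.0124) for Cxcl1. Lcn2 rose by 3.50, or 4.09 without DCAA 1. Depp1 rose by 2.01 (adjusted p = 0.0303; 2.62 with the ratio class as a block, not passing), Nnmt by 1.48 (0.0276) and Lrg1, leucine-rich alpha-2-glycoprotein, by 1.18 (0.0472). The 3 genes that fell had an adjusted p of 0.0476. In all, 17 probe sets rose, 1 of them without a single gene symbol and the rest of 13 genes. Those that fell were 3, and 3086 had an unadjusted p under 0.05. The last of the 13 genes was Mmd2, through a probe set that was not its brightest. Genes that did not pass included the transcriptional inhibitor Id3 at -1.40 (0.0593), Srebf1 at -1.0 (0.0850), the carboxylesterase Ces1d at -1.08 (0.0909) and the glutathione transferase Gstm3 at -1.11 (0.0938). Gstz1, the enzyme that metabolises dichloroacetate, stood at -0.24 (limma adjusted p = 0.689) with DCAA and 0.06 (0.992) with DCAC. Across the alternatives it ran from -0.38 to 0.012 with DCAA and from -0.12 to 0.20 with DCAC. Pdk4, a kinase that inhibits pyruvate dehydrogenase, stood at -0.98 (0.275) and -0.95 (0.919), or -0.058 and -0.64 with the 3'/5' ratio class as a block, Pdk1 at 0.04 and 0.09, Pdk2 at 0.34 and 0.08, and Cyp2e1 at 0.47 and 0.29, none passing.

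Of the 35 acute phase genes 7 rose over all genes tested and 21 adjusted over the list alone, and the list's median was 0.45 (0.37 to 0.64 across the alternatives). The adjusted p of this list was 1.01e-11 with camera, 0.477 with an estimated correlation and 0.0266 with fry, which tests whether the genes of a list move one way. Complement and coagulation genes had a median of 0.34 (0.18 to 0.39), with none passing over all genes and 10 higher adjusted over the list alone, among them C8a at 0.89 and C9 at 0.80. Neutrophil markers had a median of 1.03, or 0.43 to 1.45 across the alternatives, with Lcn2 passing over all genes and 4 higher adjusted over the list alone, and Prtn3 stood at 2.68, with the same control at the floor. Hepatocyte markers had a median of 0.34 over 16 genes, or -0.033 with quantile normalization, and none passed either way; with the ratio class as a block the median was 0.081 and the call was lost (adjusted p = 0.929). Proteasome genes had a median of -0.18 (-0.25 to -0.13) over 39, with Psmd7 at -0.85 the 1 that was lower adjusted over the list alone. Camera called these 5 of 40 lists, with the same limit from other splits as for DCAC. None was called with an estimated correlation, where the adjusted p was 0.783 for the last 4.

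All 3 DCAA arrays had high 3'/5' ratios and both controls low ones. With the ratio class as a block 0 probe sets were called, with all 20 keeping their direction, a median size of 1.66 after 1.61, and a median SE of 0.364 after 0.217. That correction is the difference of DCAC 3 from DCAC 1 and 2. It rests on a single array of the other compound, so the kept directions do not show that RNA quality had no part. With all 9 arrays limma called 0, with 3025 at an unadjusted p under 0.05; without control 2, the count of 20 became 7 without control 1, 4 without control 3, 36 without DCAC 3, 87 without DCAA 1, 5 without DCAA 2 and 3 without DCAA 3, and the 5 lists became 11, 9 and 13 without control 1, control 3 and DCAA 1.

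**Figure D2:**
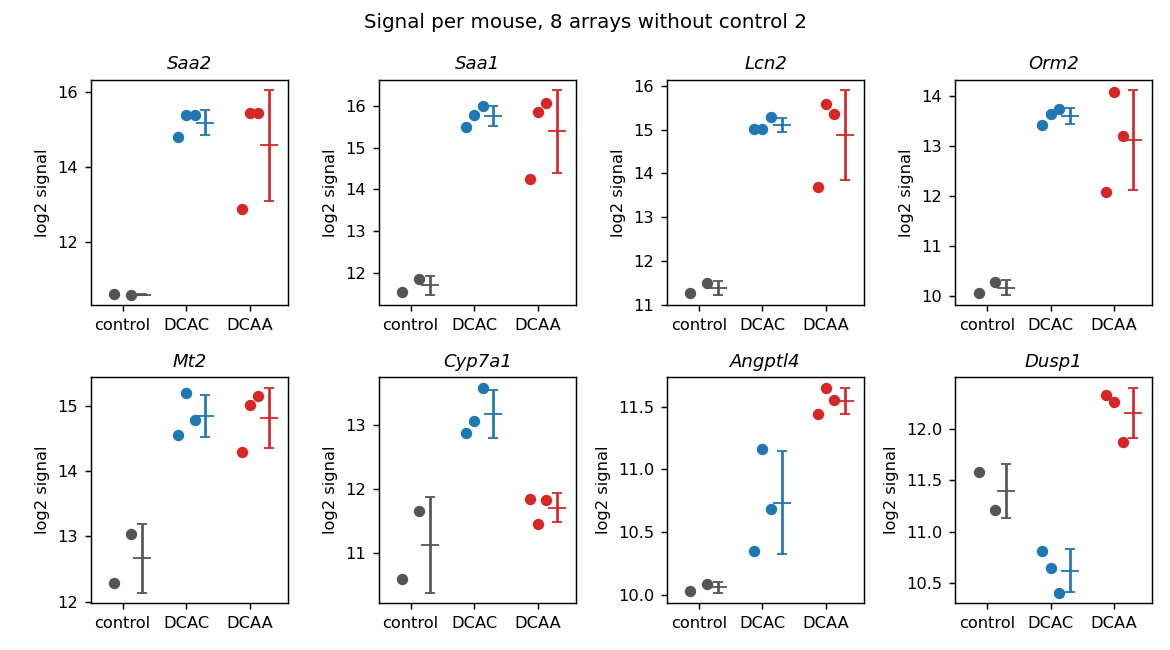
The log2 signal of 8 genes for each mouse on the 8 arrays without control 2; points are mice, and the bar beside each group is its mean with the SD. All treated mice lie above both controls for Saa2, Saa1, Lcn2, Orm2 and Mt2; DCAA 1 is the lowest treated array for Saa2, at 12.88.

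The direct comparison of DCAC with DCAA asks whether the chloride and the anhydride, given at the same molar dose, differ in their effect. Dusp1, a phosphatase that inactivates MAP kinases, had a signal of 1588 ± 223 (SD, n = 3) with DCAC and 4600 ± 748 (SD, n = 3) with DCAA, and 2715 ± 494 (SD, n = 2) in controls. The difference was -1.53 in log2 (95% interval -1.91 to -1.15, limma adjusted p = 0.0269), with all 3 DCAC arrays below all 3 DCAA arrays. It was the 1 probe set that passed, without control 2, and 2277 had an unadjusted p under 0.05. Cyp7a1, which rose with DCAC, was 1.45 higher with DCAC than with DCAA (interval 0.91 to 2.0), and that difference did not pass (adjusted p = 0.285). Bcl6, a transcriptional repressor, stood at -1.82 and Angptl4 at -0.81 (interval -1.23 to -0.40), neither passing (0.285 and 0.403).

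No difference between the compounds passed among the acute phase genes, which does not show equal effects. The difference was 0.61 for Saa2 (interval -0.50 to 1.72) and 0.37 for Saa1 (interval -0.41 to 1.15), and the list's median difference was -0.12. For Mt1 it was -0.14 by the brighter probe set (interval -0.53 to 0.26). By the dimmer one, at 1.70 with DCAC and 3.09 with DCAA, it was -1.39 (interval -1.99 to -0.78, limma adjusted p = 0.403). All 21 probe sets called with either compound had the same sign with both and 7 were called with both, which the shared controls favour. For 13 of the 21 the interval of the difference included 0, and the smallest adjusted p of a difference among them was 0.285. Camera called 0 of 40 lists, with 11 at an unadjusted p under 0.05, and fry called 0. With the 3'/5' ratio class as a block camera called 10 lists. DCAC 3 shares the high 3'/5' ratio of the DCAA arrays and the other DCAC arrays do not. The block thus sets DCAC 3 alone against the 3 DCAA arrays, also for the 10 lists, and is not a comparison of 3 mice with 3. In that fit 3 probe sets passed and Dusp1 stood at -1.74 (limma adjusted p = 0.0555). With all 9 arrays limma called 0, with 1446 at an unadjusted p under 0.05, and without control 2 the count of 1 became 2 without control 1 or control 3, and 0 without DCAA 2 or any 1 of the DCAC arrays.

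Pooling both compounds gives 6 treated mice against 2 controls. Here 18 probe sets rose and 0 fell, and 1770 had an unadjusted p under 0.05. Saa2 rose by 4.29 (SE 0.52, limma adjusted p = 0.00459), Saa1 by 3.89 (SE 0.36, 0.000728) and Lcn2 by 3.61 (SE 0.36, 0.000958), each higher on all 6 treated arrays than on both controls. Prtn3 rose by 2.73 (0.0150) from a signal of 134 ± 125 (SD, n = 2) to 731 ± 73.6 (SD, n = 6). The 2 controls lay far apart, 1 of them at the floor, and the change ran from 1.71 to 3.74 across the alternatives. Slc3a1, a subunit of an amino acid transporter, rose by 1.16 (0.0288). Srm at -1.06 (0.0759), Srebf1 at -0.91 (0.0915) and Angptl8 at -1.62 (0.115) did not pass. Of the 35 acute phase genes 7 rose over all genes and 19 adjusted over the list alone, and of the 33 complement and coagulation genes none passed over all and 14 were higher adjusted over the list alone. The adjusted p of these lists was 0.187 and 0.388 with an estimated correlation, and 0.00832 and 0.0463 with fry. With all 9 arrays limma called 0, with 2584 at an unadjusted p under 0.05. No control has a high ratio, so with the ratio class as a block the change rests on DCAC 1 and 2 against the controls. DCAA then adds nothing to its size. Without control 2, the count of 18 became 5 with the ratio class as a block and became 9 without control 1, 4 without control 3 and 9 without DCAA 2.

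**Figure D3:**
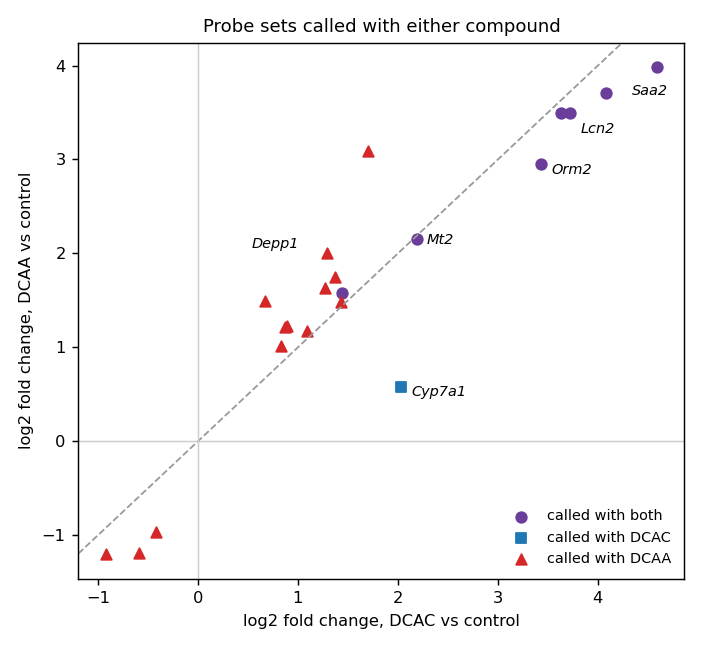
The log2 fold change against control with DCAC (horizontal) and with DCAA (vertical) of the 21 probe sets called with either compound on the 8 arrays without control 2; the dashed line marks equal change. All 21 lie in the quadrants of equal sign, and 7 were called with both compounds.

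Across all genes, fold changes with DCAC and with DCAA were correlated, which the shared controls alone also produce. Without control 2 Pearson's r over 24531 probe sets was 0.569, and it was 0.600 for simulated groups without change set against the same 2 controls. The covariance was 0.112, against 0.0834 simulated, and 69.5% of probe sets had the same sign, against 70.5% simulated. With all 9 arrays r was 0.742, against 0.502 simulated, and the covariance 0.259, against 0.0935. The simulation gave every array the same spread, while control 2, which both comparisons share, stood far from the rest. The higher values with 9 arrays therefore cannot be read as a shared response. Genes are not independent replicates, and 2 or 3 controls are too few to divide between the comparisons. Of the probe sets that rose, 8 with DCAC and 17 with DCAA, 7 were shared, where independent draws give 0.00554 and 20 simulations of unchanged groups with shared controls gave 0. Neither value allows for both real effects and shared controls, and part of the excess may come from the controls.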

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

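The tests in this part were chosen after the results were seen, except the counts over other splits with 9 arrays; the correlation of DCAC 3 with the change under DCAA and the splits of 8 arrays were set up before their outcome but after the arrays had been examined.

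The library labelled control 2 had far less of most hepatocyte transcripts examined, and its median correlation with the other arrays was 0.806, where theirs were 0.861 to 0.904. Liver RNA diluted by other RNA is argued against, since 15 hepatocyte genes with a mean signal above 5000 kept a median of 0.558% of their level (0.0163% to 112%), 12 of them under 5%. Degraded RNA or a failed array is argued against by its 3'/5' ratio of 3.63, below the median of 5.21 of the other 8 and between the 3.32 and 3.93 of the other controls. A candidate explanation is RNA of another organ: 20 kidney markers, leaving out those already seen to lead, stood 5.41 above the other arrays in median log2 (1.35 to 8.53; 7 of them also above the array median in the 8 livers), and markers of small intestine, lung, heart and brain stood at -0.48 to 0.10. The kidney genes Umod and Slc34a1 read 27216 and 29632 against 36.1 to 69.6 and 134 to 236. The marker values thus go with kidney-type RNA on this array, by a rule written after the data were seen. How such a sample came to be here was not tested, and the labels cannot say.

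Acute phase genes were higher as a list with both compounds on the 8 arrays, with medians of 0.31 and 0.45. With DCAC 27 of the 35 genes stood above 0 and 6 passed over all genes. With an estimated correlation camera called the list with neither compound (adjusted p = 0.381 and 0.477). RNA quality as the whole cause is argued against for 4 of the genes with DCAC. These passed over all genes within the low-ratio arrays, DCAC 1 and 2 against control 1 and 3, with Saa1 at 3.96 and Lcn2 at 3.63. For the list as a whole, with a median of 0.32 there, the tests disagreed. Camera called it (adjusted p = 2.05e-10), but not with an estimated correlation (adjusted p = 0.918). Fry, the bar of this test before the present one, was first met unadjusted and then not met adjusted (adjusted p = 0.195). As the bar was set after the data were seen, the call of the list is not counted here. The same explanation stays open for DCAA, where no array has a low ratio and 0 of the genes passed with the ratio class as a block. The correction by that block comes from DCAC 3 against DCAC 1 and 2, so it cannot decide the question for DCAA. With the block the median was 0.37, called by camera (adjusted p = 0.000232), but not by fry (adjusted p = 0.422) or with an estimated correlation (adjusted p = 0.826). Time of collection could also contribute and stays open, since Dbp, a clock output gene, and the acute phase mean had a Spearman rho of -0.371 over the 6 treated arrays (exact permutation p = 0.497, 0.497 adjusted over 3 relations; Pearson's r = -0.139, exact p = 0.775, and -0.872 without the 2 arrays farthest in Dbp). That relation leaves out the controls, whose Dbp lay below that of all treated mice. It thus cannot tell time of collection from treatment. A response to the compounds stays open as the biological explanation.

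More probe sets were called with DCAA than with DCAC, 20 against 8, on the 8 arrays. RNA quality could account for part of it and stays open: across probe sets, DCAC 3 minus DCAC 1 and 2 correlated at 0.245 with the change under DCAA, which shares no array with it. That value lies between the bounds set before it was computed, and no DCAA array with a low ratio exists to decide it. A stronger effect of DCAA stays open, and the difference between the compounds passed for Dusp1 alone.

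The 6 treated arrays of each named gene and the 9 arrays of each quality measure were searched for values far from the rest. Of 30 such groups 9 had one, where chance gives about 1.5. DCAA 3 had a median signal of 214, where the others had 157 to 186. Leaving it out with control 2 gave 7 probe sets up with DCAC, 3 up with DCAA, 1 lower with DCAC than with DCAA and 13 up in treated mice. DCAA 1 was low for Saa2 (log2 signal 12.88, others 14.79 to 15.44), Saa1 (14.25, others 15.51 to 16.07), Lcn2 (13.69, others 15.01 to 15.58) and Prtn3 (9.21, others 9.47 to 9.62). Srm on DCAC 1 stood at 10.94, where the others had 10.29 to 10.52. Gstz1 on DCAA 3 stood at 12.96, where the others had 13.65 to 13.98. Cyp2e1 on DCAC 1 stood at 15.26, where the others had 15.53 to 15.69. Dusp1 differed between the compounds by -1.53.

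Other splits of the same arrays were counted. With 9 arrays, 3 against 3 give 10 splits, too few for a share under 0.05; the real counts were 0 probe sets in each comparison (highest other 0), and 14, 13 and 0 lists for DCAC, DCAA and their difference (highest other 21, 20 and 6). For treated mice against controls the real count was 0, which all 84 splits reach whatever the data, so the count decides nothing (highest other 1). Without control 2, DCAC against DCAA again has 10 splits, too few. The real counts were 1 probe set (highest other 1, and 2 splits reached it) and 0 lists (highest other 12). In 9 of those 10 splits camera called at least 1 list. With 9 arrays it did so in all 10 splits for each compound against control, the real one among them. For 6 treated mice against 2 controls, 2 of 28 splits (7.14%) gave at least the real 18 probe sets, so chance is not excluded. The other split, with 22, set DCAA 2 and DCAA 3, both of the high ratio class, against the rest. The real split with the class as a block gave 5, for a change that then rests on DCAC 1 and 2 against the controls.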

How the results depend on the processing

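The fit of 8 arrays, every alternative run on it, and the 3'/5' ratio class were chosen after the data were seen; the cause of a change was not tested unless given. With 9 arrays, array weights called 1 probe set for DCAC and 20 for treated mice, and 8 and 6 lists for DCAC and DCAA. The shared response of DCAC and DCAA was 0.535 with them. Here and below that name stands for Pearson's r of both fold changes, which shared controls alone also produce. It does not measure a common effect: on the 8 arrays it was 0.569, against 0.600 for simulated groups without change. Without trend 4 were called for treated mice. An estimated correlation called 0 and 0 lists for DCAC and DCAA, fry directional 0 and 0, fry mixed 0 and 6. For DCAC against DCAA, no filter gave 3 lists, only the groups compared 2 probe sets and 1 list, and the ratio block 4 lists. Leaving out single arrays gave 0 to 8 probe sets for DCAC, 0 to 20 for DCAA, 0 to 1 for their difference and 0 to 18 for treated mice, 12 to 24, 5 to 19 and 0 to 3 lists, and a shared response of 0.569 (without control 2) to 0.843 (without control 1).

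With 8 arrays without control 2, in the order DCAC, DCAA, their difference, no filter (more tests) called 1, 4 and 0 probe sets, and 10 and 4 lists for the last 2; no trend called 0, 0 and 0, and 2 for treated mice. Robust spread called 1 for DCAC. Array weights called 30 for DCAC, 141 for DCAA and 62 for treated mice. A common median called 0 for the difference. Only the groups compared called 2 for the difference, 8 lists for DCAA and 1 for the difference. A filter on every array gave 3 lists for the difference. The replicate block called 7 for treated mice and 1 list for the difference. The ratio block called 2, 0 and 3, 5 for treated mice, and 7, 11 and 10 lists. For the 20 probe sets called with DCAA the block raised the median SE from 0.217 to 0.364. With the block the difference is DCAC 3 alone against the DCAA arrays. The change with DCAC, and that in treated mice, is then DCAC 1 and 2 alone against the controls. Low-ratio arrays alone gave 4 lists for DCAC, and high-ratio arrays alone leave DCAC 3 as the only DCAC array for the difference. An estimated correlation called 0 and 0 lists, fry directional 0 and 1, fry mixed 4 and 11. Leaving out single arrays gave 2 to 14, 3 to 87 and 0 to 2 probe sets, 4 to 27 for treated mice, 7 to 13, 5 to 13 and 0 to 4 lists, and a shared response of DCAC and DCAA, 8 arrays without control 2, of 0.444 (also without DCAC 3) to 0.680 (also without control 3); without a control, the lone one left is assumed to vary like the other groups. Reversed were hepatocyte markers with quantile normalization, at -0.019 for DCAC, -0.033 for DCAA and -0.023 for treated mice; Kupffer and macrophage markers without control 3, at 0.45 for DCAC and 0.40 for treated mice (-1.20 and -1.04 without control 1); and interferon response genes without control 3, by camera, with medians of -0.019 for DCAC and 0.0048 for treated mice (-0.57 and -0.54 without control 1). The median also changed sign, with the call lost, for oxidative phosphorylation with DCAC under quantile normalization (-0.011) and heat shock genes in treated mice without control 1 (0.020). Over all settings, called lists otherwise kept camera's direction and the call in 538 and lost the call in 103, and named genes that had passed did so in 465 and 265, with none reversed. No detection calls were used, so signal over background is not known per probe set.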

Other observations

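The test of the clock genes in this part was chosen after their values were seen.

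Values of further gene groups are given here for the 8 arrays without control 2, and only Angptl4 passed over all genes tested. Srebf1, which drives fatty acid synthesis, stood at -0.81 with DCAC and -1.0 with DCAA (limma adjusted p = 0.344 and 0.0850), and Pnpla3, a lipase under its control, at -1.53 (-2.26 to -0.81 when 1 of the controls was left out) and -1.24. Of 24 lipogenesis genes 3 were lower with DCAC and 1 with DCAA adjusted over the list alone, and Fasn, fatty acid synthase, stood at -0.90 with DCAC, while camera called the list with neither (adjusted p = 0.0851 and 0.492). Glutathione transferases were lower in part with DCAA: 3 of 19 passed adjusted over the list alone, with Gstm3 at -1.11, Gsta3 at -0.90 and Gsta2 at -1.53, and the list was not called (0.158). On the list of PPARA target and fatty acid oxidation genes Angptl4 rose with DCAA, and Cyp4a14, a PPARA target, stood at -1.91 (0.163) and Ppara at 1.01 (0.165).

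Of the lists of antigen presentation and interferon response, camera called none with DCAA. With DCAA the interferon list had a median of -0.19 (adjusted p = 0.0881), with the GTPase gene Irgm2 at -1.33 and the chemokine gene Cxcl9 at -1.37, none passing over all genes, and with DCAC Cxcl9 stood at -1.19. H2-Aa stood at -1.07 and -0.86 and Cd74, the invariant chain, at -0.87 and -0.88. Ccl5 stood at -2.46 and -2.47. Markers of Kupffer cells and macrophages had a median of -0.40 with DCAC, called by camera (0.00968) and not with an estimated correlation (adjusted p = 0.80), and it was 0.45 without control 3. Ribosomal protein genes had a median of 0.19 with DCAC (0.000124; adjusted p = 0.557 with an estimated correlation) and none of the 40 passed; with quantile normalization the median was 0.048 and the list was not called (0.592). B cell markers had a median of -0.17 and 0.24, and neither was called (0.197 and 0.588).

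Clock genes differed between mice within groups. Dbp had a log2 signal of 7.34 to 7.60 in the 2 controls and 7.86 to 11.73 in the 6 treated mice, and Npas2, of the opposite phase, 8.12 to 8.20 and 5.61 to 7.45. Controls and treated mice thus did not overlap for either gene, while they did for the means given below. For these 2 genes a difference in clock phase cannot be told apart from treatment. Per2 stood at 1.08 in treated mice (limma adjusted p = 0.373), and none of 19 clock genes passed in any comparison. A candidate explanation is the time of day at collection, a hypothesis found on these data. The mean of Dbp, Tef, Per3, Nr1d2 and Usp2 and that of Arntl, Npas2, Clock and Nfil3 ran opposite over the 8 arrays, with a Spearman rho of -0.929 (exact permutation p = 0.00223, 0.00670 adjusted over 3 relations) and Pearson's r of -0.938 (exact p = 0.000273, adjusted 0.000818), and -0.820 without the 2 farthest arrays. A change of clock phase by the treatment itself would give the same relation, and the labels give no times.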
